A study of Mus musculus with 11 samples.

How the data were processed

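Gene expression was measured in cortex of 22 mice on 11 Agilent mouse arrays with 62976 spots each, of which 59305 were not controls and held 55681 distinct probes. Per the labels, each array carried RNA of 1 mouse labelled with Cy5 (red) and of another labelled with Cy3 (green), in 5 kinds of pairing: 2 arrays of WTC with WT, 1 of TC with WT, 3 of T with WT, 2 of TC with T and 3 of TC with WTC. The arrays are named A to F and I to M. Labels give a separate mouse for every channel, so p-values measure the spread between animals. The series' description speaks of several hybridisations of each sample, while each mouse appears on 1 array here.

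The authors deposited scanner output of Agilent Feature Extraction 10.7.3.1, per the file headers. The deposited spot and background values are linear intensity values, per the file headers the median pixel brightness by Feature Extraction, neither background-subtracted nor normalized by the authors. Its LogRatio, per the file headers a log10 ratio of processed red over green signal, was used only as an alternative, and was exactly 0 for 19.6% of non-control spots on average. The authors also deposited a table of log2 ratios (log base taken from limma's usual output, not stated) and adjusted p-values for 3 comparisons, made with limma per the file header, whose version is not given in the sources used here. Its adjusted p-value column for WTC minus WT has 766 cells with numbers above 1, which were not read. It holds comparisons and no arrays, so it could not serve as an alternative input.

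For 3 arrays (I, J and K) the channel 2 labels contradict the titles. They call the Cy3 mice of arrays I and K T where the titles give TC. They call that of array J TC where the title gives T. Groups were taken from the titles, which give the group sizes of the series' description; both readings were run.

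The plan named mean signals, but median signals were the ones in the files and were used. Background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, and log2 ratios were normalized by loess within each array with control and outlier spots at weight 0. Outlier spots were left out, which left 154 probes without a value on some array, and spots of a probe were averaged; no spot was saturated (0 flags). Probes well above background in at least 5 of 22 channels were kept (35415), and for each gene the probe with the highest mean intensity, giving 25998 features. Accessions were matched to symbols through the RefSeq gene table of the mouse assembly provided: 26762 probes (48.1%) matched 1 symbol, 28919 did not and keep their accession, and 16033 of the features have a symbol. No genome was given, so no coordinates are printed. Among the symbols, 4311 had more than 1 probe passing the filter. The probes of Gfap, Crem and Mgst1 share their direction in every comparison with a ratio above 0.1 in size, while the probes of Creb1 disagree on WTC minus WT, at -0.27 and 0.20, and on TC minus T, at -0.07 and 0.25.

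Log2 ratios were fitted with lmFit and eBayes (two-sided), with coefficients for T, WTC and TC against WT and a dye term, leaving 7 residual degrees of freedom, and tested for WTC minus WT, TC minus T, T minus WT, TC minus WTC and the difference of both lesion effects, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels per animal are log2 channel values after loess and Aquantile normalization, with each probe's dye effect removed. Before the data were examined, 39 gene lists were fixed; 38 had at least 5 measured members and were tested with camera (preset correlation 0.01, adjusted over lists within a comparison), with an estimated correlation and fry as alternatives. The 39th, of sex-linked genes, had 4 measured members and a median T minus WT log2 ratio of 1.23. Which lists to describe was chosen after their tests were seen.

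Genes were named by a rule fixed before the data were examined: up to 8 genes per direction with the largest log2 ratio among those that passed, with a symbol and the same sign on every array that pairs both groups; where fewer than 3 passed, the 3 with the smallest p, said not to pass; up to 4 members with the smallest p of each list described; and always Creb1, Crem, Gfap, Vim and Aif1. Prm1 and Dgkk fall outside the rule.

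Alternatives planned before the data were examined were other background corrections, normalizations, dim-probe filters and probe rules, no dye term, slide as a block, array weights, a trended robust prior, a separate-channel fit (intraspot correlation 0.315, 17 residual degrees of freedom), subsets of arrays, both readings of the labels and leaving out each array. Added after seeing the data were a sex term, arrays left out for unlike sex or for Prm1 level, tissue covariates, fits within slides and separate-channel fits with array as a random block, with all animals, without 2 of them, without the TC mouse of array I and without the T mouse of array F.

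The scripts were tested on simulated channels with 50 genes changed at each fold among 25998 features. For WTC minus WT the ratio fit recovered 38%, 70%, 92% and 100% of genes changed 1.5-, 2-, 4- and 8-fold, and for TC minus WTC 42%, 90%, 94% and 100%. The simulation draws genes independently, unlike the animals here.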

Results

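RNA from the cortex of the right hemisphere was measured in 22 mice aged 5 to 7 months, on 11 Agilent 2-colour arrays. Each array carried 1 mouse labelled with Cy5 and another labelled with Cy3. The mice fell into 4 groups: intact wild type (WT, n = 6), intact transgenic (T, n = 5), wild type with a cryolesion (WTC, n = 5) and transgenic with a cryolesion (TC, n = 6). The transgenic mice carried a tetracycline-controlled pair of transgenes that makes astrocytes, the main support glia of the brain, produce VP16-CREB. This is a constitutively active form of the transcription factor CREB. The cryolesion was a focal cold injury made with dry ice applied for 30 s, and tissue was taken 3 days later. No mouse was on more than 1 array, so each array gave 1 independent ratio between 2 animals. Between 56.6% and 65.3% of the spots of a channel were well above background, and the number of arrays limits the precision of every value. All log2 ratios are given with their standard error (SE) from a limma fit to all 11 arrays. Adjusted p-values of genes are Benjamini-Hochberg values over 25998 features unless said to be over a gene list alone.

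The transgenes were addressed first through the genes of the CREB family. The position of the Creb1 probe relative to the VP16-CREB construct is not known here, so it is no check of the labels. It gave a T minus WT log2 ratio of 0.05 ± 0.15 (adjusted p = 0.98) and a TC minus WTC log2 ratio of 0.25 ± 0.14 (adjusted p = 0.44). Crem, a CREB-family gene that is itself a known CREB target, gave 0.36 ± 0.16 (adjusted p = 0.98) without a lesion and 0.59 ± 0.16 (adjusted p = 0.19) after it. Its mean log2 level was 9.36 ± 0.22 (SD, n = 6) in WT, 9.63 ± 0.18 (n = 5) in T, 9.24 ± 0.30 (n = 5) in WTC and 9.90 ± 0.38 (n = 6) in TC.

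The first comparison asked what the cryolesion changed in wild-type cortex. Over their lists alone, many genes of reactive astrocytes, phagocytes and dividing cells rose after the lesion. For synapses and mitochondrial respiration 2 and 1 genes fell. With an estimated correlation the rising and the falling lists all lost their calls. The adjusted p was 0.25 for reactive astrocytes, 0.26 for phagocytes, dividing cells and synapses and 0.33 for respiration. In the fit over all genes, 6 genes rose and 0 fell at an adjusted p under 0.05. Timp1, an inhibitor of matrix metalloproteinases, rose by 3.61 ± 0.42 on the log2 scale (12.2-fold, adjusted p = 0.046). In the separate-channel fit it rose by 4.71 ± 0.58. Traf1, a signalling adaptor of tumour necrosis factor receptors, rose by 1.61 ± 0.18, and Mgst1, a membrane-bound glutathione transferase, by 1.34 ± 0.16, each with an adjusted p of 0.046. Tmem47 rose by 1.09 ± 0.12 and Unc13d, which acts in granule release, by 1.05 ± 0.11, also with an adjusted p of 0.046. Lgi4, a secreted glial protein, rose by 1.05 ± 0.09 (adjusted p = 0.029). Each of the 6 was higher in the lesioned mouse on both arrays that paired a WTC with a WT mouse.

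Among 22 measured genes of pan-reactive astrocytes, the median log2 ratio was 1.94. Adjusted over the list alone, 18 rose and 0 fell, against 1 over all genes. Gfap, the intermediate filament of astrocytes, rose by 3.47 ± 0.46 (list-adjusted p = 0.00035, adjusted p = 0.056 over all genes). Vim, another intermediate filament, rose by 3.60 ± 0.55 and the protease inhibitor Serpina3n by 3.11 ± 0.47 (list-adjusted p = 0.00042 for both). Of 22 genes of homeostatic astrocytes 9 rose over the list alone (median 0.52). Among them, the water channel gene Aqp4 rose by 1.59 ± 0.29, the transcription factor Sox9 by 0.83 ± 0.10 and Mlc1 by 0.81 ± 0.12. Of 25 cell cycle genes 24 rose over the list alone (median 1.84). Among them, Prc1 rose by 2.49 ± 0.45, Cdc20 by 2.12 ± 0.41, Cdk1 by 1.94 ± 0.37 and Bub1b by 1.31 ± 0.24.

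Phagocyte genes moved the same way. Of 22 monocyte and macrophage genes 17 rose over the list alone (median 1.69). Among them, Lyz1, a lysozyme, rose by 3.28 ± 0.71, S100a4 by 2.84 ± 0.70, S100a6 by 2.77 ± 0.54 and Saa3, an acute-phase protein, by 2.29 ± 0.46. Of 23 genes of phagocyte lysosomes and lipid handling 19 rose (median 1.49). Lgals3, a galectin, rose by 3.87 ± 0.61, Gpnmb by 3.34 ± 0.64, Cst7 by 2.44 ± 0.52 and the tetraspanin Cd9 by 1.85 ± 0.38. Of 18 complement genes 14 rose (median 1.26), among them C3 by 3.64 ± 0.56, C4b by 2.53 ± 0.45 and Serping1 by 1.72 ± 0.27. Of 18 genes of homeostatic microglia 14 rose (median 1.21). Among them, C1qc, also a complement gene, rose by 1.68 ± 0.42, Aif1 by 1.61 ± 0.40, the receptor gene Csf1r by 1.29 ± 0.32 and Gpr34 by 1.15 ± 0.28. Of 25 synapse and neuronal cytoskeleton genes 2 fell over the list alone (median -0.25), Cplx1 by 0.98 ± 0.21 and Vamp2 by 0.54 ± 0.14, both genes of vesicle fusion. Thy1 at -0.42 ± 0.12 and Stmn3 at -0.48 ± 0.15 did not pass. Of 27 oxidative phosphorylation genes 26 had negative log2 ratios (median -0.21). Over the list alone 1, Cox5a, fell by 0.42 ± 0.10, while Atp5b (-0.37 ± 0.11), Ndufv1 (-0.30 ± 0.10) and Cox4i1 (-0.24 ± 0.09) did not pass. On the same arrays choroid plexus and ependyma genes were higher (13 measured, median 1.86, 3 up over the list alone) and striatal genes lower (13 measured, median -0.79, 0 over the list alone).

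With camera at a preset inter-gene correlation of 0.01, 25 of 38 lists passed in this comparison, 20 up and 5 down, including every list named above. The adjusted p was 4.5e-14 for pan-reactive astrocytes, 6.1e-18 for cell cycle and 6e-07 for oxidative phosphorylation. With a correlation estimated from the data 0 lists passed. The adjusted p was then 0.25 for both astrocyte lists and 0.26 for the cell cycle, macrophage, phagocyte, complement, microglia and synapse lists. It was 0.33 for oxidative phosphorylation and choroid plexus, and 0.36 for striatum. With fry 14 lists passed. The fry adjusted p ran from 0.016 for pan-reactive astrocytes to 0.039 for macrophages over the astrocyte, cell cycle, macrophage, phagocyte, complement and microglia lists. It was 0.07 for synapses, 0.089 for oxidative phosphorylation and choroid plexus and 0.22 for striatum, which did not pass. The count of 6 genes depended on the arrays: leaving out arrays A, B, C, D, E, F, I, J, K, L and M in turn gave 1, 0, 0, 10, 1, 2, 1433, 0, 1558, 0 and 1 genes. A separate-channel fit of the same 22 channels called 6904 features, 3794 up and 3110 down, among them all 6 genes. It also compares mice of different arrays and has no term for the slide that held them. All WT mice were on slide 1, while WTC mice were on slides 1 and 2, so slide may contribute to its calls. Adjusted over all genes, that fit called 8 synapse genes down (median -0.34), 14 oxidative phosphorylation genes down (median -0.33) and 1 striatal gene down (median -0.84). It called 19 pan-reactive astrocyte, 24 cell cycle and 21 macrophage genes up.

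**Figure D1:**
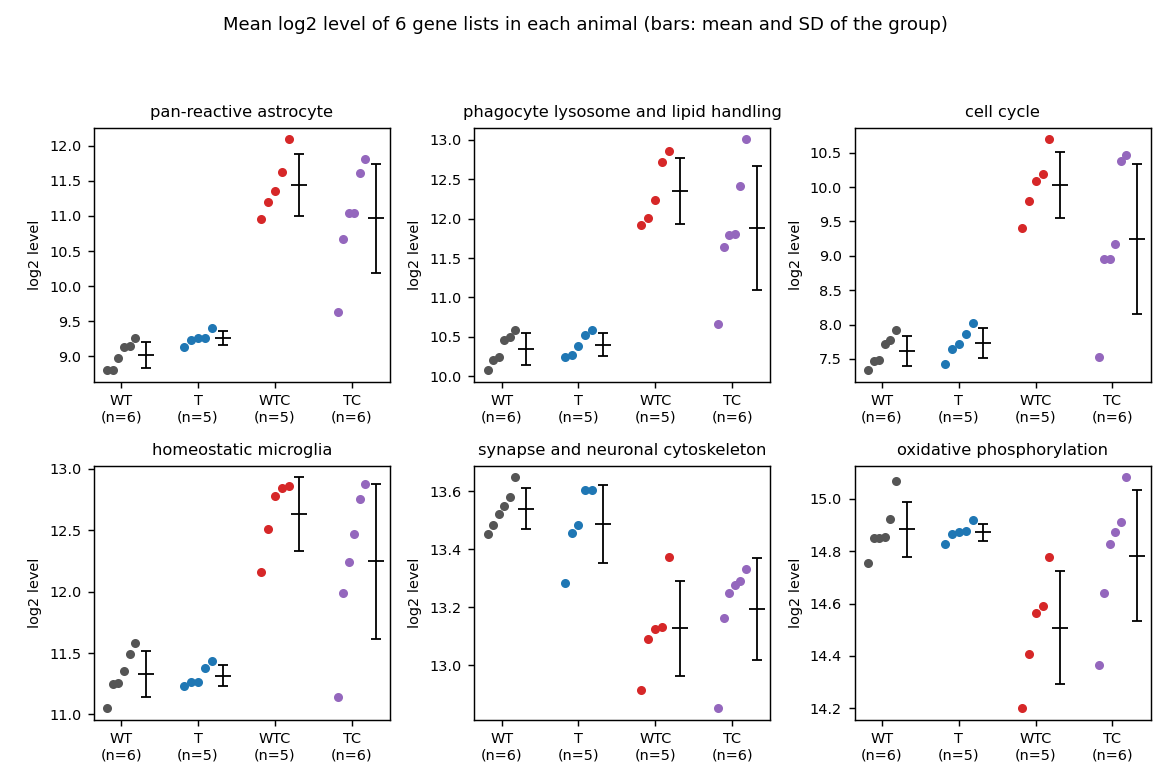
Mean log2 level of 6 gene lists (vertical axes) in each of the 22 mice, by group; each point is 1 animal, and the bars beside the points give the group's mean and SD. The pan-reactive astrocyte level lay between 10.95 and 12.09 in the 5 WTC mice and between 8.80 and 9.26 in the 6 WT mice, while the 6 TC mice spread from 9.63 to 11.81.

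The same question was asked in transgenic mice. At 3 days after the lesion, some genes of reactive astrocytes, phagocytes and antigen presentation rose in TC against T cortex over their lists alone, while the levels of 1 TC mouse, given below, stood apart. In limma 0 genes passed at an adjusted p under 0.05, against 3099 features at an unadjusted p under 0.05 where 1300 are expected by chance. The 3 genes with the smallest p were Lgi4 (0.84 ± 0.09), Mgst1 (1.30 ± 0.15) and Plce1, a phospholipase (1.24 ± 0.15), each with an adjusted p of 0.11, which does not pass. Of 22 pan-reactive astrocyte genes 8 rose over the list alone (median 1.35). Among them, Timp1 rose by 3.11 ± 0.41, Vim by 2.98 ± 0.54, Gfap by 2.41 ± 0.45 and S1pr3, a sphingosine phosphate receptor, by 1.99 ± 0.39. Of 22 homeostatic astrocyte genes 11 rose (median 0.48). Among them, Aqp4 rose by 1.38 ± 0.29, Gpr37l1 by 0.66 ± 0.13 and Sox9 by 0.48 ± 0.10. Of 23 phagocyte genes 10 rose over the list alone. Among them, Lgals3 rose by 3.00 ± 0.60, Gpnmb by 2.64 ± 0.62, Spp1, osteopontin, by 2.23 ± 0.55 and Npc2 by 0.74 ± 0.19. Of 18 antigen presentation genes 6 rose (median 0.90). Among them, Cd74 rose by 1.49 ± 0.42, H2-Eb1 by 1.41 ± 0.37, H2-Aa by 1.15 ± 0.34 and the peptide transporter Tap2 by 0.76 ± 0.24.

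Of 22 macrophage genes (median 1.06) and 25 cell cycle genes (median 1.02) all had positive log2 ratios and 0 passed over the list alone. Lyz1 stood at 2.41 ± 0.69, Lyz2 at 1.80 ± 0.59, Ccnb2 at 1.41 ± 0.45 and Cdc20 at 1.30 ± 0.40. Of 42 CREB target genes 3 rose and 3 fell over the list alone (median -0.19). Atf3 rose by 1.31 ± 0.32 and Gadd45g, a stress gene, by 0.60 ± 0.13, while Fosb fell by 0.66 ± 0.15 and Vgf by 0.57 ± 0.14. The CREB target median was -0.05 without arrays I, J and K and 0.09 with the other reading of their labels, where the list did not pass (adjusted p = 0.67 and 0.68) and camera's direction turned. Of 13 striatal genes 8 fell over the list alone (median -1.26). The dopamine receptor gene Drd1 fell by 1.78 ± 0.56, Rgs9 by 1.53 ± 0.55, the enkephalin gene Penk by 1.49 ± 0.50 and Gpr6 by 1.13 ± 0.42. The level of this list had an SD of 1.14 between the 6 WT mice. With camera's preset correlation 25 of 38 lists passed, 19 up and 6 down, including these 8. With an estimated correlation 0 passed: the adjusted p was 0.27 for homeostatic astrocytes, 0.35 for the pan-reactive, phagocyte, antigen presentation and striatum lists, 0.39 for the macrophage and cell cycle lists and 0.41 for CREB targets. With fry 0 lists passed as well. The separate-channel fit called 1904 features, 1244 up and 660 down. Adjusted over all genes, it called 18 of the 25 cell cycle genes (median 1.41), 12 of the 22 macrophage genes (median 1.48), 17 phagocyte, 12 pan-reactive astrocyte, 12 antigen presentation and 5 homeostatic astrocyte genes (median 0.30) up. It called 0 striatal genes (median -1.20). In the ratio fit, leaving out array A, E or I gave 4, 1 or 6 genes in place of 0.

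The TC mouse of array I, which its channel 2 label calls T, stood apart from the other 5 TC mice. Its score on the first principal component was -30.5, inside the range of the 11 intact mice (-45.0 to -22.2), while the other TC mice had 1.6 to 84.2. Its pan-reactive astrocyte level was 9.63, against 10.67 to 11.81 in the other TC mice and 9.14 to 9.40 in T mice. In the same order, its cell cycle level was 7.52 (8.95 to 10.46 and 7.42 to 8.02), its macrophage level 8.06 (9.32 to 10.94 and 7.82 to 8.36) and its phagocyte level 10.66 (11.63 to 13.01 and 10.25 to 10.59). Its excitatory neuron level of 9.20 was under both ranges (10.61 to 11.24 and 10.98 to 11.70), and its hemoglobin level was 11.72 (10.36 to 11.10 and 11.28 to 12.10). Its Gfap level of 13.96 (14.42 to 15.66 and 11.94 to 12.75), Vim level of 13.61 (14.58 to 15.83 and 11.62 to 12.55) and Timp1 level of 9.70 (11.50 to 13.71 and 6.65 to 7.86) lay between both. Its Aqp4 level of 12.34 and Dgkk level of 9.90 lay among those of the other TC mice (12.01 to 12.50 and 9.36 to 10.66). The channel 2 labels also call the T mouse of array J TC and the TC mouse of array K T. Their first-component scores were -35.6 and 84.2.

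In TC minus T, leaving out array I moved the macrophage median to 1.70, the cell cycle median to 1.74 and the CREB target median to -0.11, which no longer passed (adjusted p = 0.41). Without array J the cell cycle median was 0.65, and without array C the antigen presentation median was 0.56. A separate-channel fit with array as a random block, chosen after seeing the data, gave TC minus T medians with all animals and without the TC mouse of array I. They were 1.77 and 2.14 for pan-reactive astrocytes, 1.49 and 1.89 for macrophages, and 1.42 and 1.87 for cell cycle. That fit called 1880 features with all animals and 3248 without this mouse.

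The lesion effects of both genotypes were set against each other. Across 25998 features, which are not independent replicates, the WTC minus WT and TC minus T log2 ratios had a Pearson correlation of 0.68. Because both contrasts rest on the same network of arrays, 100 simulations with no effect gave a mean correlation of 0.34 and at most 0.40. The covariance was 0.085 against a simulated mean of 0.017, a difference of 0.069. The simulations drew genes independently, unlike the correlated genes here. Their range may therefore be too narrow, and it cannot tell whether 0.68 lies beyond chance.

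**Figure D2:**
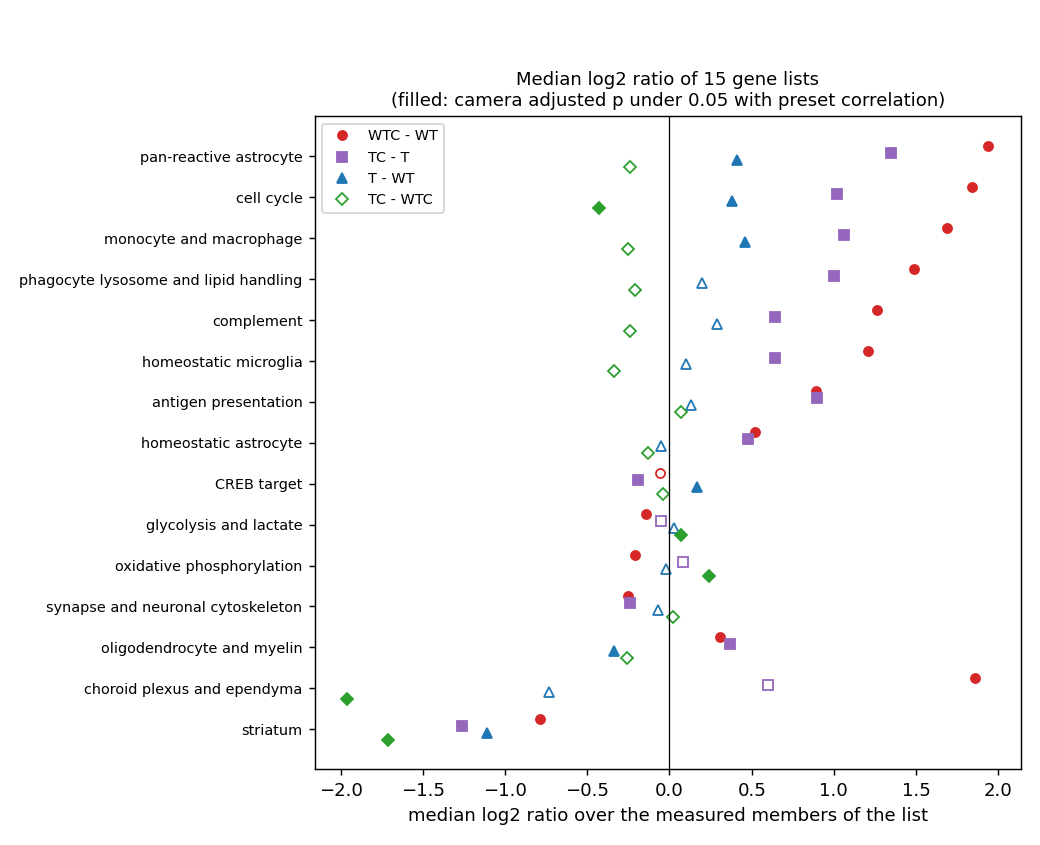
Median log2 ratio (horizontal axis) over the measured members of 15 gene lists in 4 comparisons; filled symbols passed camera with the preset correlation. The pan-reactive astrocyte list had medians of 1.94 for WTC minus WT and 1.35 for TC minus T, and the striatum list was negative in all 4 comparisons drawn.

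The next comparison asked what active CREB in astrocytes changed in intact cortex. In limma 0 genes passed between T and WT at an adjusted p under 0.05, with 762 features at an unadjusted p under 0.05, fewer than the 1300 expected by chance, and 0 in the separate-channel fit. The smallest p-values belonged to Dbp, a circadian transcription factor (-0.52 ± 0.08), Gkn3 (-0.97 ± 0.18) and Selenov (-0.36 ± 0.07), each with an adjusted p of 0.98. The 13 striatal genes had a median of -1.11 and 6 fell over the list alone. The striatum level was 9.14 in the T mouse of array F and 11.12 to 11.68 in the other 4. The median was -0.90 without array F, and in the separate-channel fit with array as a random block it was -0.74 with all animals and -0.38 without this mouse. Over all genes the planned separate-channel fit called 0 striatal genes in T minus WT (median -0.75), and gave medians of 0.25 for pan-reactive astrocytes and 0.19 for cell cycle. Penk fell by 1.60 ± 0.46, Rxrg by 1.59 ± 0.50, the phosphodiesterase gene Pde10a by 1.37 ± 0.45 and the dopamine receptor gene Drd2 by 0.84 ± 0.24. Of 42 CREB target genes 30 had positive log2 ratios (median 0.17) and 0 passed over the list alone. The smallest p-values were those of Penk, Fos (0.99 ± 0.29), Fosb (0.47 ± 0.14) and Nfil3 (0.37 ± 0.12). Of 22 pan-reactive astrocyte genes 20 were positive (median 0.41), with Lcn2, lipocalin, at 1.66 ± 0.48, Serpina3n at 0.91 ± 0.42 and Gfap at 0.88 ± 0.42. All 25 cell cycle genes were positive (median 0.38), with Mcm6 at 0.60 ± 0.30 and Bub1b at 0.50 ± 0.22, and 0 of either list passed alone. Of 19 myelin genes 18 were negative (median -0.34), among them Mag at -0.49 ± 0.33 and Cnp at -0.47 ± 0.23, and 0 passed. With camera's preset correlation 10 of 38 lists passed, 6 up and 4 down, including these 5. With an estimated correlation 0 passed, and the adjusted p was 0.82 for each of them. Leaving out array D or E gave 17 lists with either, and the myelin median was 0.02 with the other reading of the labels of arrays I, J and K. Without array J the myelin median was -0.10 and did not pass (adjusted p = 0.31). The pan-reactive astrocyte median was 0.24 without array C and 0.24 without array I. The cell cycle median was 0.25, 0.67, 0.17 and 0.24 without arrays B, E, I and K, and the CREB target median 0.27, 0.26 and 0.11 without arrays D, E and I.

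The central comparison of the design set lesioned transgenic against lesioned wild-type cortex. Over their lists alone, 8 genes of respiration and 5 of glycolysis rose and 11 striatal genes fell in TC against WTC, and the list calls were lost with an estimated correlation (adjusted p = 0.91, 0.20 and 0.91). In limma 0 genes passed over all genes at an adjusted p under 0.05, with 3837 features at an unadjusted p under 0.05 where 1300 are expected by chance. All 27 oxidative phosphorylation genes had positive log2 ratios (median 0.24) and 8 rose over the list alone. Cox5a rose by 0.57 ± 0.08, Atp5b by 0.49 ± 0.10 and cytochrome c, Cycs, by 0.48 ± 0.09. Of 27 glycolysis and lactate genes 5 rose over the list alone (median 0.07). Ppp1r3c, a glycogen-targeting subunit, rose by 0.74 ± 0.14, Pgk1 by 0.50 ± 0.09, Pgam1 by 0.46 ± 0.09 and Gapdh by 0.39 ± 0.07. Of 42 CREB targets, whose median of -0.04 and camera direction (up, adjusted p = 0.41) differ in sign, 2 rose and 1 fell over the list alone. Fos rose by 1.17 ± 0.28, Nfil3 rose by 0.48 ± 0.12 and Penk, which is also a striatal gene, fell by 2.92 ± 0.45. The CREB target median was 0.20 within slide 1, which holds 1 TC mouse, and 0.09 within slide 2. In the separate-channel fit with array as a random block it was -0.02 with all animals. Without the TC mouse of array I it was 0.11.

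Cell cycle genes had a median of -0.43, with Rrm2 at -1.22 ± 0.56, Prc1 at -0.72 ± 0.40 and Bub1 at -0.42 ± 0.25 but Pcna at 0.40 ± 0.20, and 0 passed over the list alone. With tissue covariates, added after seeing the data, the cell cycle median was 1.02, with Rrm2 at 1.48, Prc1 at 1.07 and Bub1 at 0.61, and within slides 1 and 2 it was -0.99 and -0.16, with 1 TC mouse on slide 1. In the separate-channel fit with array as a random block it was -0.65 with all animals and -0.39 without the TC mouse of array I. Without arrays A, B, C and L it was -0.39, -0.28, -0.43 and -0.26 and no longer passed camera (adjusted p = 0.077, 0.23, 0.06 and 0.56), and without array K it was -0.77. Gfap (-0.18 ± 0.41, adjusted p = 0.87), Vim (0.18 ± 0.48, adjusted p = 0.89) and Aif1 (-0.48 ± 0.35, adjusted p = 0.55) did not pass. Of 13 striatal genes 11 fell over the list alone (median -1.71). The separate-channel fit gave a median of -1.13 with 0 striatal genes called over all genes, and the mean striatum level was 9.79 ± 0.80 (SD, n = 6) in TC and 10.60 ± 1.38 (n = 5) in WTC. Adora2a fell by 2.42 ± 0.57, Rgs9 by 2.26 ± 0.49 and Ppp1r1b by 1.71 ± 0.36. The 13 choroid plexus and ependyma genes had a median of -1.96, with Clic6 at -2.57 ± 0.87, Ccdc153 at -2.36 ± 0.81, Cfap126 at -1.32 ± 0.47 and Foxj1 at -1.04 ± 0.36, and 0 passed over the list alone. This median was -1.31 with a dye effect for each slide and -1.23 without array M. The tissue covariates are the array means of this list, the striatum list and the thalamus and hippocampus list. Since the choroid plexus and striatum medians were themselves shifted here, these covariates may also take up part of the effect tested. With them the median was -0.02 (camera adjusted p = 0.86), which is fixed by construction and decides nothing. The 3 genes with the smallest p over all genes were Nop14 (0.62 ± 0.09), Gnpnat1 (0.41 ± 0.06) and Cox5a, each with an adjusted p of 0.13. Another Gnpnat1 probe gave 0.03. Prm1, a protamine gene normally transcribed in spermatids, and Dgkk, a diacylglycerol kinase gene, were chosen after their values were seen. Their log2 ratios were 5.67 and 2.85, neither passing (adjusted p = 0.132 for both), and both passed in the separate-channel fit (adjusted p = 0.0107 and 0.00119). Prm1 was well above background in all 6 TC mice but in 3 of 5 WTC mice, so the size of its ratio is uncertain.

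With camera's preset correlation 5 of 38 lists passed between TC and WTC: oxidative phosphorylation (adjusted p = 3.4e-12) and glycolysis (0.0037) up, and striatum (1.1e-08), choroid plexus (1.8e-05) and cell cycle (0.022) down. With an estimated correlation 0 passed: the adjusted p was 0.91 for oxidative phosphorylation and striatum, 0.20 for glycolysis and 0.92 for choroid plexus and cell cycle. Leaving out array J, K or M gave 8, 13 or 9 lists, and leaving out array I gave 2 genes in place of 0. Without array K the oxidative phosphorylation median was 0.37 and the glycolysis median 0.14. The TC mouse of array I had an oxidative phosphorylation level of 15.08, above the other TC mice (14.37 to 14.91). In the separate-channel fit with array as a random block these medians were 0.27 and 0.10 with all animals. Without this mouse they were 0.20 and 0.07. The separate-channel fit called 42 features, 36 up and 6 down, among them 0 oxidative phosphorylation genes (median 0.27) and 1 glycolysis gene (median 0.10), and the authors' deposited table holds 6622 spots at an adjusted p under 0.05 for this comparison.

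**Figure D3:**
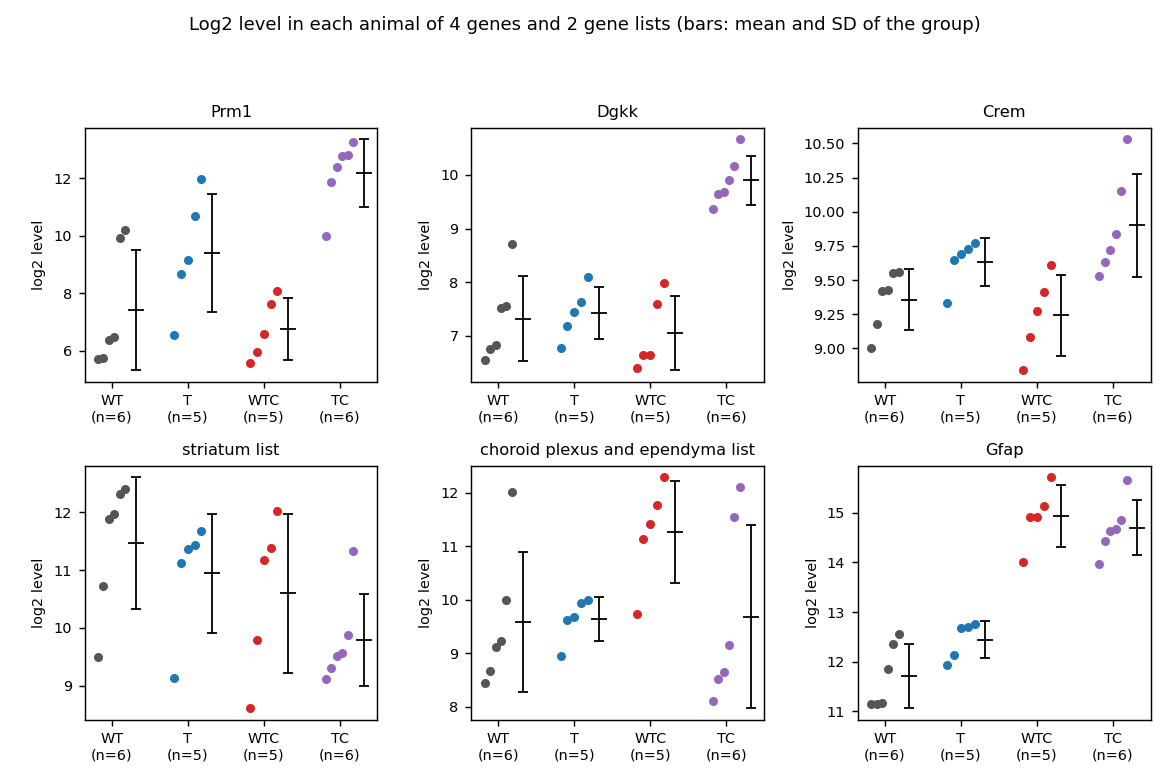
Log2 level (vertical axes) of Prm1, Dgkk, Crem and Gfap and mean log2 level of the striatum and choroid plexus lists in each of the 22 mice, by group; bars give the group's mean and SD. Dgkk was at 9.36 or above in all 6 TC mice and at 8.71 or below in the other 16, and the striatum level ran from 9.49 to 12.41 within the 6 WT mice.

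The last comparison tested whether the lesion effect differed between genotypes. In limma 0 genes passed, with 1386 features at an unadjusted p under 0.05 against 1300 expected by chance and 0 in the separate-channel fit. The smallest p-values were those of Cox5a (0.56 ± 0.11), Iqcc (-0.36 ± 0.07) and Rgl1 (-0.82 ± 0.16), each with an adjusted p of 0.81. Another Iqcc probe gave -0.02. All 27 oxidative phosphorylation genes had positive differences (median 0.27), and 1, Cox5a, passed over the list alone. All 25 cell cycle genes (median -0.80) and all 22 macrophage genes (median -0.64) had negative differences, as did 19 of 22 pan-reactive astrocyte genes (median -0.59), and 0 of these passed over their lists alone. The separate-channel fit called 0 genes of any list named here. Lcn2 stood at -2.03 ± 0.61, C3 at -2.12 ± 0.64, Rrm2 at -1.85 ± 0.73 and S100a6 at -1.37 ± 0.61. Of 11 neutrophil genes (median -0.21) S100a9 at -2.76 ± 0.69 and S100a8 at -1.92 ± 0.50 passed over the list alone. Their WTC minus WT log2 ratios were 2.56 and 1.93, their TC minus T log2 ratios -0.20 and 0.01 and their T minus WT log2 ratios 2.15 and 1.44. With camera's preset correlation 13 of 38 lists passed, 4 up and 9 down. With an estimated correlation 0 passed, and the adjusted p was 0.75 for each list named here. Leaving out array J or L gave 20 or 8 lists.

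The list differences depended on the fit and on single arrays. With tissue covariates, which may take up part of the effect tested, the medians were 0.58 for cell cycle, 0.17 for pan-reactive astrocytes and 0.52 for macrophages. Within slide 1, which holds 1 TC mouse, these medians were -1.11, 0.10 and -0.06. The cell cycle median was -0.51 without array B and -0.51 without array I. The pan-reactive median was -0.39, -0.23, -0.94 and -0.32 without arrays B, I, K and L. The macrophage median was -0.97, -0.29 and -0.98 without arrays E, I and K. Without array L it was -0.17 and the neutrophil median -0.11, and neither list passed (adjusted p = 0.37 and 0.11). In the separate-channel fit with array as a random block, leaving out the TC mouse of array I moved the cell cycle median from -0.86 to -0.55, the pan-reactive median from -0.60 to -0.31 and the macrophage median from -0.67 to -0.38, and that fit called 2 features without this mouse.

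The arrays lay on 2 slides, A to F on slide 1 and I to M on slide 2. Slide 1 holds 1 TC mouse, that of array C, so every slide 1 value of TC minus T, TC minus WTC and the difference rests on 1 TC animal, which is assumed to vary like the other groups, and is no replication of slide 2. In the ratio fit with a dye effect for each slide the 5 comparisons, in the order above, called 5, 0, 0, 0 and 0 genes. The separate-channel fits had no slide term. Slide 2 holds no WT mouse and all TC mice but that of array C. Slide may therefore contribute to the calls of those fits, which was not tested. Within slide 1 alone, a fit of 6 arrays, WTC minus WT called 2128 genes from only the 2 WTC mice of arrays A and B. T minus WT called 0 there. Slide 2 alone, which holds no WT mouse, gave 0 for TC minus T and 0 for TC minus WTC. Pan-reactive astrocyte medians were 1.93 for WTC minus WT with the slide term and 2.17 within slide 1, and for TC minus T 1.36 with the term, 1.83 within slide 1 and 0.69 within slide 2. The oxidative phosphorylation median for TC minus WTC was 0.26 with the term, 0.22 within slide 1 and 0.22 within slide 2, and the striatum median -1.68, -1.82 and -1.75. Within slide 1 the T minus WT medians were 0.13 for pan-reactive astrocytes, 0.10 for cell cycle and -0.06 for myelin, which did not pass (adjusted p = 0.34). The antigen presentation median for TC minus T was 2.31 within slide 1 and 0.24 within slide 2, and the choroid plexus median for TC minus WTC was -1.01 and -1.50.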

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

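Chosen after the results were seen were the tests of striatal tissue, of few members and of swapped animals. So were the tests of leaving out 2 animals or the T mouse of array F, and the sex-term fits. The spermatid test followed the choice of Prm1, which was made after its values were seen. Its prediction was written before its own result was seen. The relabellings were planned.

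In 6 of 92 groups tested 1 animal stood far from the others, where chance gives about 1 in 20. The synapse list level was 12.85 in the TC mouse of array K (others 13.16 to 13.33), and the CREB target list level was 9.75 in the WT mouse of array A (others 10.07 to 10.23). The striatum list level was 9.14 in the T mouse of array F (others 11.12 to 11.68) and 11.33 in the TC mouse of array J (others 9.12 to 9.88). Crem was at 9.33 in the T mouse of array F (others 9.65 to 9.77) and Vim at 12.55 in the T mouse of array I (others 11.62 to 11.83).

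The lesion effect differed between genotypes for 13 lists by camera's preset-correlation test of the difference, none of them with an estimated correlation. Their median differences were -0.59 for pan-reactive astrocytes, -0.45 for A2-type astrocytes, -0.44 for homeostatic microglia, -0.64 for macrophages, -0.40 for phagocyte lysosomes, -0.21 for neutrophils, -0.45 for complement, -0.80 for cell cycle and -1.26 for choroid plexus. They were 0.04 for glycolysis, 0.27 for oxidative phosphorylation, 0.14 for cholesterol synthesis and 0.34 for hemoglobin.

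Striatal genes were lower in T than in WT mice, with a median of -1.11, and all 13 measured members shared the sign, which argues against a few members driving the list. The T mouse of array F (9.14, others 11.12 to 11.68) bears on the size: in a separate-channel fit with array as a random block the median was -0.74 with all animals and -0.38 without it, and without array F it was -0.90. The mean level was 10.95 in T and 11.47 in WT, 11.40 in T without this mouse and 11.86 in WT without its lowest mouse, that of array A. With a sex term the median was -0.89, which argues against unlike sexes on an array as the whole cause. The level of the list had an SD of 1.14 between the 6 WT mice, which share genotype and treatment. This SD is a spread between single animals, not between group means, and it includes the low WT mouse of array A. It therefore cannot tell whether unequal amounts of striatal tissue in the dissected samples account for the shift, and this stays open. An effect of the transgenes stays open as well.

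Prm1 had a TC minus WTC log2 ratio of 5.67 that did not pass (adjusted p = 0.132). It was well above background in 3 of 5 WTC mice, so the size of the ratio is uncertain. Prm2, Tnp1 and Tnp2, other spermatid genes, had a median of 0.10. Prm2 and Tnp1 were well above background in all 6 TC mice. Prm2 ran from 6.33 to 6.72 in TC and from 6.36 to 6.77 in WTC mice, and Tnp1 from 6.49 to 6.71 and from 6.35 to 6.57. Neither rose with Prm1, which argues against spermatid transcripts only as far as these dim probes can respond. With a sex term the Prm1 ratio was 6.47, which argues against unlike sexes. All 6 TC mice were at 9.98 or above and all 5 WTC mice at 8.08 or below. A swap between these groups would narrow that gap. Prm1 was chosen after its values were seen, however, so the gap is no independent test of swaps. Above 8.08 also lay 2 of the WT mice, those of arrays A and D. Under it lay 1 T mouse, that of array F, which also had the low striatum and Crem levels given above. These numbers differ by 1, which decides nothing, so single wrong labels among the intact mice stay open. An effect of the transgenes stays open too.

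The authors' deposited table holds 6622 spots at an adjusted p under 0.05 for TC minus WTC, where limma called 0 genes here (3837 features at an unadjusted p under 0.05, 42 features by separate channels). A regression of its log2 ratios on the 22 channels gave weights between -0.01 and 0.01 to the WTC mouse of array A and the TC mouse of array K. A separate-channel fit with array as a random block called 6221 features without these 2 animals and 34 with them, so their absence could contribute to the gap. The table counts calls among 59305 spots, while the fits here count them among 25998 features that passed a filter. The counts are therefore not on the same scale, and the share of the gap accounted for is not known. Of 30 ways to leave out 1 WTC and 1 TC mouse, in a simpler fit, this pair gave 4011 calls, the next 444 and the median way 3. The first of these had the lowest first-component score of the WTC mice (3.3) and the other the highest of the TC mice (84.2); why they carry no weight is not given in the sources used here.

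Of 100 relabellings of the animals, the real one included, 4 called as many genes as the 6 for WTC minus WT. This rank is borderline and was not adjusted for the other comparisons tested. The count of 6 also moved widely when single arrays were left out, so the rank does not exclude chance. The highest other relabelling called 728, which may point to a structure of the samples, but this was not tested. Leaving out each array in turn gave real counts of 0 to 1558. Any relabelling reaches a count of 0, so the relabellings decide nothing for the counts of 0 in limma: all 100 relabellings reached the real 0 for TC minus T (highest other 672, 3099 features at an unadjusted p under 0.05, 1904 by separate channels), T minus WT (35, 762 and 0), TC minus WTC (1000, 3837 and 42) and the difference (606, 1386 and 0).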

How the results depend on the processing

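The sex term, the fits without arrays of unlike sex or without arrays A, D and F, the tissue covariates, the fits within a slide and the separate-channel fits with array as a random block, with or without some animals, were chosen after seeing the data. Of the planned values, 32 of 140 gene counts and 20 list counts moved by over 1.5 times or, where the count was 0, to any other count. Most of the moved gene counts were those for WTC minus WT, which moved whenever 1 array was left out. Of 693 values of described lists, all from camera with the preset correlation, 16 no longer passed and 3 reversed. These values leave out fry and the estimated correlation, with which 0 lists passed in any comparison. Of 4551 values of named genes 94 no longer passed, 239 newly passed and 20 reversed. Among the added ones, 18 of 47 gene counts and 6 of 25 list counts moved, 21 of 165 list values no longer passed and 8 reversed, and of 1536 gene values 12 no longer passed, 364 newly passed and 47 reversed. The others kept their direction and side of the threshold, for lists only under the preset correlation. Where the direction or call changed, the cause was not tested. Between 56.6% and 65.3% of spots were well above background, which limits the dim genes.

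The 6 genes for WTC minus WT became 0 with median centring, 1 with LogRatio, 1 without a filter on dim probes, 50 with probes well above background in all channels, 1 with the mean of a gene's probes, 1 with slide as a random block, 6904 with separate channels, 0 with only arrays that carry both groups, 9953 with array weights, 1 with an intensity trend and robust prior, 1741 without arrays I, J and K and 0 with the other reading of their labels. Among the added fits they became 337 with a sex term, 367 without arrays of unlike sex, 0 without arrays A, D and F, 0 with tissue covariates, 2128 within slide 1, 6930 with separate channels and array as a random block, 10884 when that fit left out 2 animals, 8369 when it left out the TC mouse of array I and 6676 when it left out the T mouse of array F. The 0 genes in limma for TC minus T (3099 at an unadjusted p under 0.05) became 1904 with separate channels, 1854 with array weights, 1880 with array as a random block, 1791 when that fit left out 2 animals, 3248 when it left out the TC mouse of array I and 1924 when it left out the T mouse of array F. The 0 genes in limma for TC minus WTC (3837 at an unadjusted p under 0.05) became 42, 1 with only arrays that carry both groups, 3 with the other reading of labels, 34 with array as a random block, 6221 without 2 animals, 46 without the TC mouse of array I and 23 without the T mouse of array F. The 0 genes in limma for the difference (1386 at an unadjusted p under 0.05, 0 by separate channels) became 2 without the TC mouse of array I. Leaving out each array gave 0 to 1558 genes for WTC minus WT, 0 to 6 for TC minus T, 0 to 0 for T minus WT and for the difference and 0 to 2 for TC minus WTC.

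With an estimated correlation 0 lists passed in any of the 5 comparisons, and with fry 14, 0, 0, 1 and 0, in the order of the report. The 25 lists for WTC minus WT became 10 with tissue covariates, and the 25 for TC minus T 16 with the other reading of labels. The 10 for T minus WT became 20 with a sex term, 21 without arrays of unlike sex and 17 without arrays A, D and F. The 5 for TC minus WTC became 18 without arrays I, J and K, 14 with tissue covariates and 11 within slide 1, and the 13 for the difference 20 without arrays I, J and K. Leaving out each array gave 24 to 29, 23 to 27, 10 to 17, 4 to 13 and 8 to 20 lists, and a correlation of lesion effects of 0.56 to 0.84.

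The CREB target median for TC minus WTC changed sign within both slides and without the TC mouse of array I, as given above. Camera's direction reversed in lists as follows. The CREB target list for TC minus T was -0.05 without arrays I, J and K (mean and direction turned), 0.09 with the other reading of labels and 0.10 within slide 1, and the myelin list for T minus WT 0.02 with the other reading. Tissue covariates hold the striatum, choroid plexus and thalamus lists by construction. They gave 0.25 for myelin in T minus WT, 1.02 for cell cycle and 0.11 for striatum in TC minus WTC. In the difference they gave 0.58 for cell cycle, 0.17 for pan-reactive astrocytes and 0.52 for macrophages. Within slide 1 the pan-reactive difference was 0.10.

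Crem in WTC minus WT was -0.17 with median centring, -0.08 with LogRatio, -0.06 with separate channels, -0.06 with array as a random block, -0.05 without 2 animals, -0.03 without the TC mouse of array I, -0.06 without the T mouse of array F and, leaving out each array, -0.09 to 0.14, and its difference -0.02 with only arrays that carry both groups. Creb1 in TC minus T was 0.09 with the mean of probes, 0.09 with only arrays that carry both groups, 0.08 with the other reading of labels, 0.03 without arrays A, D and F and 0.09 within slide 2, and in T minus WT -0.02 (without array D) to 0.11 leaving out each array, -0.11 with a sex term and -0.02 without arrays A, D and F. Aif1 in T minus WT was -0.27 with only arrays that carry both groups, -0.11 with array weights, -0.22 without arrays I, J and K, -0.07 (without array I) to 0.47 leaving out each array, -0.16 with tissue covariates, -0.24 within slide 1, -0.03 without 2 animals and -0.03 without the TC mouse of array I. Gfap in TC minus WTC was 0.06 with median centring, 0.10 with only arrays that carry both groups, 0.21 with the other reading of labels, -0.47 (without array K) to 0.03 (without array M) leaving out each array, 0.15 with a sex term, 0.31 without arrays of unlike sex, 0.06 with tissue covariates and 1.28 within slide 1. Vim in TC minus WTC was -0.22 (without array K) to 0.51 (without array L) leaving out each array, -0.02 without array C and -0.16 without 2 animals, and its difference 0.02 without arrays of unlike sex. Within slide 1 the differences were 0.25 for Aif1, 0.77 for Gfap, 0.04 for Mrc1 and 0.80 for Vim.

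Tissue covariates gave 0.09 for Cplx1 and 0.12 for Creb1 in WTC minus WT, 0.03 for Rgs9 in TC minus T, and 0.05 for Cnp, 0.31 for Mag and 0.12 for Mobp in T minus WT. In TC minus WTC they gave 0.23 for Aif1, 0.61 for Bub1, 0.76 for Ccdc153, 0.44 for Cfap126, -0.25 for Creb1, 0.39 for Foxj1, 1.07 for Prc1 and 1.48 for Rrm2. In the difference they gave 0.39 for Aif1, 0.22 for Bub1, 0.06 for Clec4n, -0.24 for Creb1, 0.03 for Il1r2, 0.47 for Mrc1, 0.49 for Prc1, 0.56 for Rrm2, 0.16 for S100a6, 0.58 for Saa3 and 0.74 for Vim. Rgs9, Ccdc153, Cfap126 and Foxj1 belong to lists that the covariates hold, so their values decide nothing. Not run were the authors' table as input, which holds comparisons and no arrays, and array weights, blocks and direct arrays for list tests.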

Other observations

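The sex-term fits and the test of leaving out 2 animals were chosen after the results were seen, as was the choice of Prm1 and Dgkk.

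Lists not described above also moved after the lesion in wild-type mice. Of 22 oxidative stress and metallothionein genes 9 rose over the list alone (median 0.38), among them the metallothionein genes Mt2 by 1.54 ± 0.22 and Mt1 by 1.04 ± 0.21, the peroxiredoxin gene Prdx6 by 1.16 ± 0.24 and Gstm1 by 0.49 ± 0.08. In transgenic mice 2 of them rose (median 0.27), Mt2 by 0.92 ± 0.22 and Mt1 by 0.85 ± 0.21. Of 30 extracellular matrix genes 8 rose in wild-type mice (median 0.55), including the metalloproteinase genes Mmp14 by 0.87 ± 0.20 and Mmp2 by 0.69 ± 0.21 and Tgfbi by 2.01 ± 0.60. Of 7 hemoglobin and erythroid genes 5 fell (median -0.86), among them Hbb-bs by 1.03 ± 0.24 and Alas2, an enzyme of heme synthesis, by 0.80 ± 0.28. Camera with the preset correlation gave adjusted p-values of 5e-06, 2.7e-05 and 5e-05 for these 3 lists in wild-type mice, and with an estimated correlation the adjusted p was 0.25, 0.33 and 0.27. In intact mice 3 of 11 neutrophil genes rose in T over WT over the list alone (median 0.09), S100a9 by 2.15 ± 0.54, S100a8 by 1.44 ± 0.40 and Lrg1 by 1.37 ± 0.41. Camera gave an adjusted p of 0.00042 with the preset correlation and 0.82 with an estimated one.

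The labels give no sex. The mean level of Y-linked genes was at 6.88 or below in 4 mice, 2 WT, 1 T and 1 WTC, and at 9.36 or above in the other 18. Arrays E, F, I and M carried 1 mouse of each kind.

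Dgkk was at 9.36 or above in all 6 TC mice and at 8.71 or below in every other mouse. The mean Prm1 level was 12.17 ± 1.17 (SD, n = 6) in TC, 9.41 ± 2.06 (n = 5) in T, 7.40 ± 2.08 (n = 6) in WT and 6.77 ± 1.07 (n = 5) in WTC. A hypothesis is that the Prm1 probe may read untranslated sequence carried by a transgene construct, since other spermatid genes had a median of 0.10; the construct's sequence was not among the data, so this was not tested.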
